A study of Homo sapiens with 8 samples.

How the data were processed

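The series measured RNA from TE-1, an established cell line from a human esophageal squamous cell carcinoma, on 8 single-colour (Cy3) oligonucleotide arrays. GEO's labels put 4 arrays in a parental group and 4 in a drug-resistant group. The titles of the resistant samples carry "5um". The series' design text names the drug as CDDP (cisplatin), a platinum compound that crosslinks DNA, and the labels do not say how the 5 um was applied, so it is not used as a dose here. The titles number the samples A to D within each group. Nothing in the labels says whether these came from separate cultures. Every p-value below that compares the groups therefore rests only on the spread between these samples, which may be technical. Per the series' design text, the arrays were hybridized for 17 hours at 65 °C and read with a SureScan Dx scanner.

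The authors deposited 1 table of normalized values, with a row for each of 173079 probes and a column for each array. Its values were taken as log2 signals already normalized by the authors, on the evidence of the deposited values alone. They ran from 2.34 to 17.4. As base 2 the maximum corresponds to a signal of 168699, and as a natural logarithm it would be 34763800, a reading far beyond array scanners. At least 94.1% of the values of parental array A recurred (to 6 decimals) in each other array, as quantile normalization leaves them. The background correction, the averaging of repeated spots and any filter on dim probes are not given in the sources used here. No detection calls or spot flags were used here, so a low value could not be told from background. A log2 difference between the groups had a median standard error of 0.22 over the probes tested, and of 0.11 without resistant A and B, so the spread of these 2 arrays limits the precision. A second file, the authors' deposited table of changed transcripts, gives numbers (another kind of value) of mRNAs, lncRNAs and circRNAs past a p of 0.05 and a fold change of 2. Its test and any adjustment are not given in the sources used here. It calls its groups g2 and g1, without saying which is which.

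No source used here pairs a probe with a gene. None of the probe IDs (0 of 173011) matched a symbol, synonym, gene ID or accession of the reference gene table (GRCh38.p14, 59792 genes). The 3 planned analyses that need gene names, namely the counts per gene, the level of HDAC9 and the tests of gene lists, were therefore not run, and every result is given per probe. HDAC9, a histone deacetylase named in the series title, is not analysed here. Probes were described by the start of their IDs: 31643 with A_, 2906 with B_, and 2 custom sets of 105509 and 32953 probes. Which RNA class each set targets is not given in the sources used here. The 68 control probes were left out of all tests. They include 10 probes for E1A, adenovirus transcripts that the array maker's kits supply as spike-ins, and probes whose IDs name human GAPDH and PGK1. The mean of the 10 E1A probes is called the spike-in signal.

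Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) over 173011 probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Probes called with a fold of 2 or more were also counted. Single control values were compared by exact two-sided permutation tests, whose smallest possible p with 4 against 4 is 0.029. These tests were not part of the planned design. Neither was the permutation test of the first principal component against the spike-in signal. The design, the threshold, the other settings and the rule for naming probes were fixed before the data were examined. Where probes carry no gene name, that rule names 2 probes that rose and 2 that fell. They are those with the largest changes among called probes whose groups do not overlap and whose mean in the higher group lies above the median probe.

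The other settings fixed then were renewed quantile normalization, a shift to equal 75th percentiles, filters at the 25th percentile and at the median of mean signal, a trended robust variance prior, array weights, the title letter as a replicate block, leaving out each array, a Student t-test, limma's treat against a fold of 1.5, and an unadjusted threshold with a fold of 2. A pseudocount was not needed on a log scale. A further 3 fits were added after the data were seen: 1 without resistant A and B, 1 with the spike-in signal as a covariate, and 1 with both changes. The covariate was first tried as the mean of 3 E1A probes (2948 higher and 2291 lower probes called over all 8 arrays) and, with that result seen, set to the mean of all 10. The letters were checked for pairing. Deviations of same-lettered arrays from their group means correlated across probes at -0.57 (A), -0.25 (B), 0.08 (C) and 0.06 (D), so the letters were not treated as pairs.

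The fit was tested on simulated data for this comparison. Arrays were drawn for all 173011 probes from the real probe means, with 200 probes changed. The noise of a probe was its parental SD scaled by each array's own spread. It was drawn independently for each probe, whereas resistant A and B deviated over many probes together. The shares below therefore do not describe recovery or false calls under such shared deviations. Of 100 probes changed by 1 on the log2 scale 39% were recovered, and of 100 changed by 2 on that scale 70% were, with 1 false call. Without resistant A and B these shares were 46% and 77%, with 8 false calls.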

Results

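The data set held 8 arrays of the esophageal squamous carcinoma line TE-1, 4 labelled parental and 4 labelled drug-resistant, with cisplatin as the drug named by the series. The series title asks which transcripts differ in cisplatin resistance and what HDAC9 does there. The deposited values were log2 signals of 173079 probes, of which 173011 were compared. The distributions were almost equal across arrays, with medians from 7.14 (resistant B) to 7.15. Probes could not be assigned to genes, so the transcripts below are given by probe ID.

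Resistant and parental cells differed in 335 probes at an adjusted p under 0.05 (limma, Benjamini-Hochberg). Of these, 184 were higher and 151 lower in resistant cells. A fold of 2 or more was reached by 213 of them, 112 higher and 101 lower. Leaving out any 1 parental array or resistant D gave 11 or 12 called probes, all of them higher and 0 lower. This was a loss of calls and need not mean that the differences rest on each of these arrays. For the 4 probes named below the log2 changes moved little in these fits. They were 3.14 to 3.19 and 3.02 to 3.12 for the rises, and -4.34 to -4.06 and -2.65 to -2.60 for the falls. Sizes of the other changes in these fits are not given here. In all 335 the values of the 4 resistant arrays lay wholly above or below those of the 4 parental arrays. The same held for 19588 of the probes tested (11.3%), so it adds little to the calls. The median size of the 335 changes was 1.11 on the log2 scale, with a median standard error of 0.13.

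The called probes came from all probe sets. Among probes with A_ IDs 56 were higher and 46 lower, which is 0.32% of the set. The larger custom set gave 98 higher and 96 lower probes, or 0.18%. The smaller custom set gave 29 higher and 8 lower, or 0.11%, and the B_ probes 1 of each. Without resistant A and B the A_ probes gave 2854 higher and 4258 lower, the larger custom set 7890 and 13352, the smaller custom set 3805 and 1659, and the B_ probes 300 and 175. With a fold of 2 or more in that fit, the higher and lower counts were 221 and 730 for the A_ probes and 214 and 1113 for the larger custom set. They were 157 and 315 for the smaller custom set and 18 and 37 for the B_ probes. The fit without resistant A and B compared only resistant C and D with the parental arrays. The median log2 signal was 7.42 for the A_ probes, 7.35 for the larger custom set, 6.23 for the smaller custom set and 6.25 for the B_ probes. The 2 sets with the smallest shares of called probes were thus also the dimmest. The difference between sets was not tested.

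The largest rises were seen with 2 probes of the larger custom set. CUST_85051_PI448380708 went from 11.82 ± 0.07 in parental to 14.99 ± 0.18 in resistant cells (SD, n = 4 each), a log2 change of 3.17 ± 0.12 (SE) or 9.0-fold, with an adjusted p of 7.8e-04 by limma. This probe and its neighbours by number formed a stretch of 3 called probes that rose by 2.72 to 3.17 on the log2 scale. CUST_41734_PI448380708 went from 9.97 ± 0.06 to 13.02 ± 0.51, a log2 change of 3.04 ± 0.24 (SE), with a limma adjusted p of 0.00998. The array values of both probes did not overlap between the groups.

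The largest falls were seen with A_23_P33196 and CUST_78901_PI448380708. A_23_P33196 went from 12.61 ± 0.15 in parental to 8.51 ± 1.12 in resistant cells (SD, n = 4 each), a log2 change of -4.10 ± 0.49 (SE) or 17.1-fold lower, with a limma adjusted p of 0.037. Resistant B had the lowest value, 6.87, and the other 3 resistant arrays read 8.75 to 9.25. CUST_78901_PI448380708 went from 9.66 ± 0.07 to 7.04 ± 0.54, a log2 change of -2.62 ± 0.25 (SE) with a limma adjusted p of 0.017. The calls of both these probes and of CUST_41734_PI448380708 were lost in each fit without 1 parental array and in the fit without resistant D. Both falling probes also lost their calls without resistant C. Where calls were lost in these fits, the log2 changes were -4.34 to -4.06 for A_23_P33196 and -2.74 to -2.60 for CUST_78901_PI448380708. For CUST_41734_PI448380708 they were 3.02 to 3.12.

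**Figure D1:**
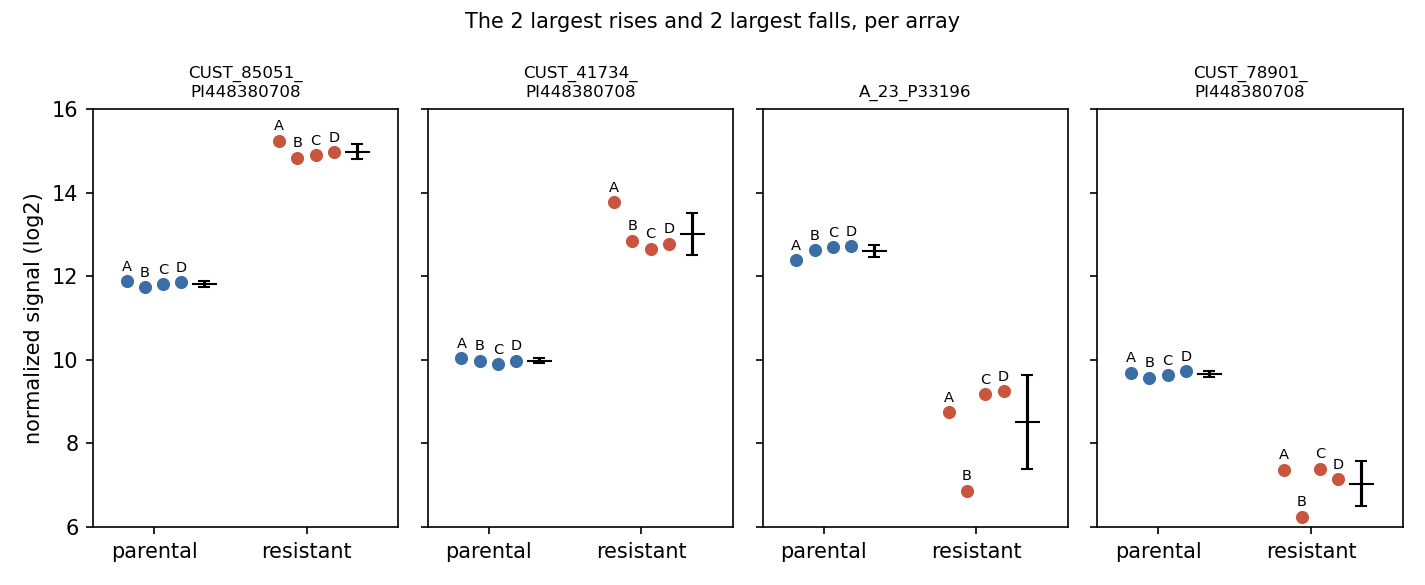
Normalized log2 signal (y axis) of the 4 named probes in each array (points, with replicate letters) by group, with the mean and SD beside the points (n = 4 per group). Parental values of each probe lie close together (SD 0.06 to 0.15), and all resistant values lie above them in the first pair and below them in the second pair.

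Arrays of the parental group were close to each other, whereas the resistant group was spread widely. Pairwise correlations across probes lay between 0.988 and 0.993 among the 4 parental arrays, and between 0.818 and 0.992 among the 4 resistant arrays. Resistant C and D correlated at 0.992. Resistant A and B correlated at 0.818, the lowest value of any pair. The standard deviation of a probe's difference from its group mean was 0.74 in resistant B and 0.60 in resistant A. It was 0.21 in resistant C, 0.22 in resistant D, and 0.17 to 0.22 in the parental arrays.

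The signal of the E1A spike-in probes was highest in resistant B, and the order of the arrays by this signal is called the spike-in line. The spike-in signal was 12.6 in resistant B, 11.5 in resistant C, 11.1 in resistant D and 10.6 in resistant A. In the parental arrays it was 11.3 in A and 10.7 to 10.8 in the other 3. The group means were 10.9 ± 0.24 for parental and 11.5 ± 0.85 for resistant arrays (SD, n = 4 each; exact permutation p = 0.29, two-sided, adjusted p = 0.67 over 7 control values). The first principal component held 74.4% of the variance of the probes and set resistant B (0.85) and A (-0.37) at opposite ends, with parental C next to resistant A (-0.23). Resistant A stood apart on the second component, which held 9.9% of the variance, with a loading of -0.70 against -0.29 to 0.36 in the other arrays. Across the 8 arrays the loading on the first component correlated with the spike-in signal (Pearson r = 0.98, exact permutation p = 4.2e-04; Spearman rho = 0.90, exact permutation p = 0.0046). This test was not planned. The r was 0.88 over the 6 arrays that remained without resistant B and C, the arrays farthest from the median spike-in signal. The component held most of the variance, so other probes may correlate with it as strongly. Their correlations were not computed, and the r does not single out the E1A probes. Median signals of the probe sets differed along the spike-in line too. The A_ probes had a median of 7.18 in resistant B and 7.38 to 7.54 in the other 7 arrays, and the smaller custom set had 6.53 in resistant B and 6.14 to 6.29 elsewhere.

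**Figure D2:**
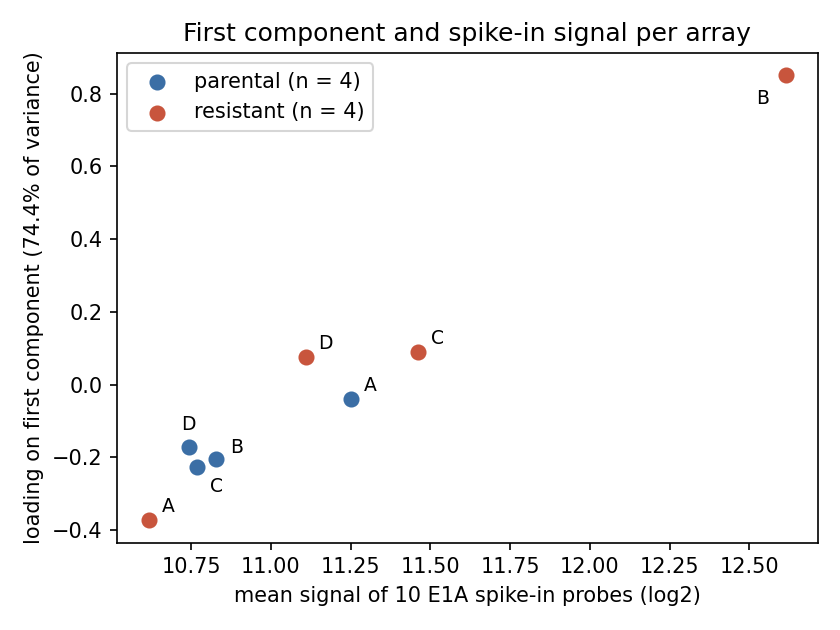
Each point is an array, with the mean log2 signal of the 10 E1A spike-in probes on the x axis and the loading on the first principal component of all compared probes on the y axis; letters are the replicate labels. Resistant B (12.6) and resistant A (10.6) lie at opposite ends, and the other 6 arrays fall between them in both measures.

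The spike-in line was also visible within the parental group. Across probes, the deviation of resistant B from its group mean correlated with that of parental A at r = 0.54. Deviations within a group sum to 0, so differences that share no array were compared as well. Resistant B minus resistant D correlated with parental A minus the other parental arrays at r = 0.50, resistant A minus resistant C at r = -0.52, and resistant C minus resistant D at r = 0.02; probes are not independent replicates.

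**Figure D3:**
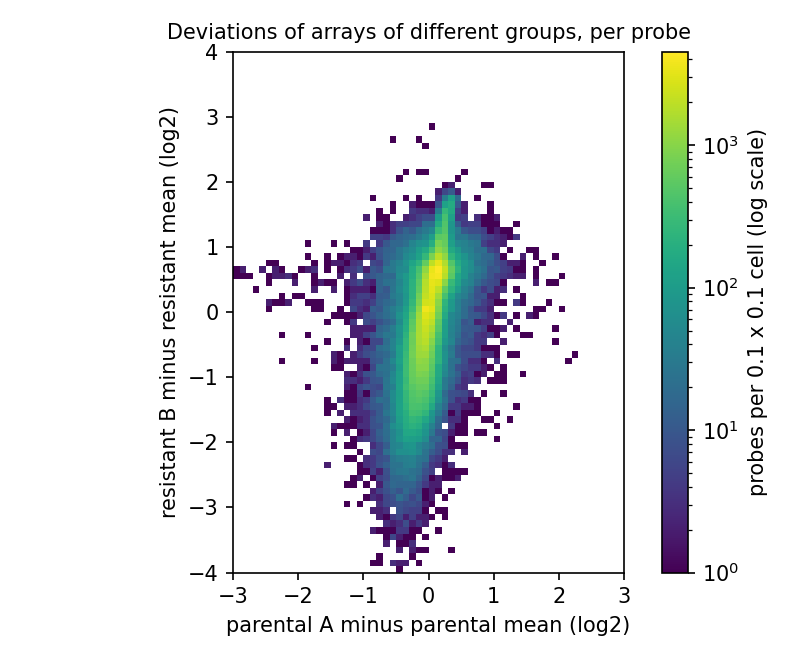
Density of probes by the deviation of parental A from the parental mean (x axis, log2) and of resistant B from the resistant mean (y axis, log2); colour gives probes per cell on a log scale, and 5 probes lie outside the range. The 2 deviations, from arrays of different groups, rose together across probes (r = 0.54).

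Probes for the glycolytic enzymes GAPDH and PGK1, present among the controls, did not pass a test between the groups. The GAPDH 3′ probe read 16.26 ± 0.05 in parental and 16.00 ± 0.34 in resistant arrays (exact permutation p = 0.11), and the GAPDH 5′ probe 13.36 ± 0.09 and 13.17 ± 0.28 (exact permutation p = 0.29; SD, n = 4 each). The PGK1 3′ probe read 13.93 ± 0.09 in parental and 13.83 ± 0.27 in resistant arrays (exact permutation p = 0.66). The PGK1 5′ probe read 9.35 ± 0.07 and 9.37 ± 0.18 (exact permutation p = 0.80). After adjustment over the 7 control values, each of these p-values was 0.67 or 0.80. Resistant B had the lowest GAPDH 3′ value of all arrays, 15.5.

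The number of called probes depended on single arrays. Without resistant A, 3233 probes were called, and without resistant B 3483. Without resistant C 15 were called, without resistant D 12, and without 1 parental array 11 or 12. In the group-only fit and in all 8 fits that left out 1 array, 11 probes were called, all of them higher. Without both resistant A and B, 34293 probes were called (14849 higher, 19444 lower) with a median change of 0.50 on the log2 scale. These calls describe resistant C and D against the parental arrays, and the left-out arrays did not always share them. Among these calls with a fold of 2 or more, 2195 were lower and 610 higher. Resistant A was on the resistant side for 16.5% of these lower probes and 82.3% of the higher ones. Resistant B was on that side for 97.5% and 47.7%. With the spike-in signal as a covariate, 6680 probes were called (3620 higher, 3060 lower). The fit without resistant A and B and the covariate fit each called all 335 probes with the same sign. The fit with both changes called 306 of them. These fits reuse arrays on which the 335 were called, so this is no independent support.

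**Figure D4:**
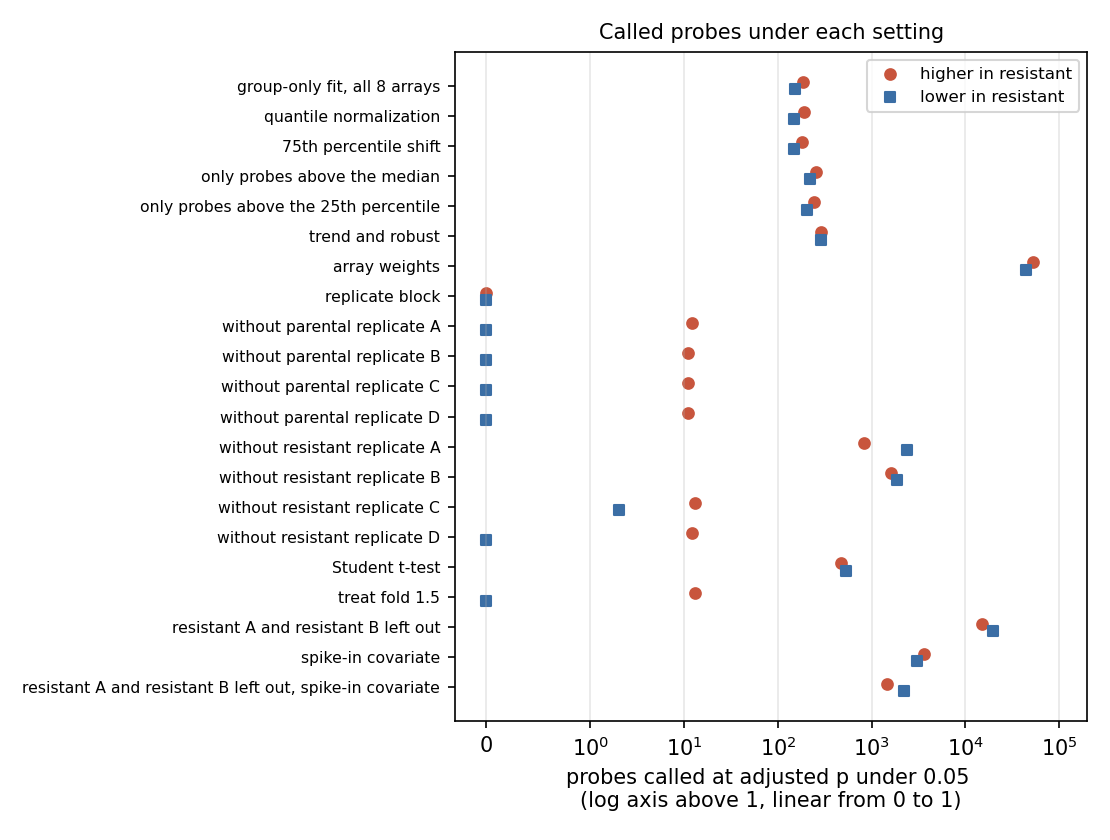
Number of probes called at an adjusted p under 0.05 (x axis, log above 1) higher or lower in resistant cells, for each way of fitting (y axis). The group-only fit over all 8 arrays gave 184 higher and 151 lower probes, fits without 1 parental array gave 11 or 12, and leaving out resistant A and B gave 14849 and 19444.

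The share of lower probes also depended on the fit. At an unadjusted p under 0.05 with a fold of 2 or more, 501 probes were higher and 1941 lower in resistant cells by limma, 79.5% lower. The share was 41.7% without resistant B (872 higher, 624 lower), 80.1% without resistant A and 76.8% without both. With the spike-in signal as a covariate it was 27.3%, and with both changes 58.3%. Among probes called after adjustment with a fold of 2, 47.4% were lower in the group-only fit, 82.0% without resistant A and 39.3% without resistant B. It was 13.3% without resistant C, 78.3% without resistant A and B, 27.9% with the spike-in covariate and 57.9% with both changes. No lower probe was called without resistant D or without 1 parental array.

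The authors' deposited table lists 282 changed mRNAs, 96 up and 186 down, at a p of 0.05 and a fold of 2. The authors' deposited table also lists 105 lncRNAs, 61 up and 44 down, and 410 circRNAs, 124 up and 286 down. Long non-coding RNAs (lncRNAs) are transcripts not classed as protein-coding, and circular RNAs (circRNAs) are transcripts closed into a ring by back-splicing. The 3 classes of the authors' deposited table sum to 797 transcripts. The deposited table does not say which of its 2 groups is the resistant one, so its up and down have no known direction. At those thresholds, unadjusted, limma gave 2442 probes on the values used here. The deposited table counts transcripts of 3 classes and its filters are unknown, so the numbers are not of the same items.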

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

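The tests in this part that compare arrays along the spike-in signal, look for degraded RNA or count splits were chosen after the results were seen, and so was the test of parental material by correlations, which replaced an earlier one. Among 36 groups of 4 arrays examined for 1 array far from the rest, 3 stood out, and chance gives about 1 in 20.

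The spike-in signal of parental A, 11.3, lay far from the other parental arrays at 10.7 to 10.8, a gap of 0.836 of the group's range. The control probe Mouse-PGK1_3 read 4.75 in resistant A and 2.45 to 2.54 in the other resistant arrays, a gap of 0.961 of the range. The latter values lay near the lowest of all deposited values, 2.34. The control probe Rat-GAPDH_3 read 6.54 in parental C and 6.65 to 6.66 in the other parental arrays, a gap of 0.913 of the range.

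Resistant B lay apart from all other arrays, and resistant A from the other resistant arrays. A candidate explanation for resistant B is less sample RNA signal relative to the spike-in transcripts. Across probes, its deviation from its group mean went with that of parental A, an array of the other group (r = 0.54). Against a general link, resistant C minus resistant D did not follow parental A minus the other parental arrays (r = 0.02), although their spike-in signals differed (11.5 and 11.1). For resistant A the opposite, more sample RNA signal, stays open: its difference from resistant C went against that of parental A from the other parental arrays (r = -0.52, no array shared), but its spike-in signal of 10.6 lay close to the 10.7 to 10.8 of 3 parental arrays, and it also stood apart on the second component (-0.70 against -0.29 to 0.36).

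Degraded RNA was looked for in the 3′ minus 5′ differences of GAPDH and PGK1. For GAPDH it was 2.17 in resistant B, 3.37 in resistant A and 2.73 to 3.03 in the other arrays, and for PGK1 4.08, 4.93 and 4.39 to 4.76, so resistant B was the lowest and resistant A the highest for both. The priming used for labelling is not given in the sources used here, and degradation stays open for both arrays. If parental material were the whole cause, a mixture would lie between the groups. It would then correlate with resistant C and D at least as well as the parental arrays do. The correlations were at most 0.961 for resistant A and B and 0.975 to 0.985 for the parental arrays, so a mixture alone would not give them. These low correlations are part of the pattern itself and were known when this bound was set. They are therefore no independent test, and any further deviation in A or B would also lower them. Resistant A was closer to every parental array (0.965 to 0.979) than to resistant C or D (0.961), so parental material in it beside another cause stays open. An earlier test of it used the probes that changed at least 2-fold in resistant C and D. Of the lower ones 16.5% had resistant A on the resistant side and 97.5% had resistant B, and of the higher ones 82.3% and 47.7%. The bound first set, a share under 50% in either array and either direction, was met by both arrays and would have counted in favour of parental material. It was then tightened to both directions in the same array, which neither array met, and later replaced by the correlations. No biological explanation was tested.

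At a fold of 2 and an unadjusted p under 0.05, 79.5% of the probes were lower in resistant cells. If this excess came from the spike-in line alone, taking the spike-in signal into the fit should end it. The share was 41.7% without resistant B, 80.1% without resistant A and 76.8% without both. It was 27.3% with that covariate over all 8 arrays, and 58.3% with the covariate but without resistant A and B, so the spike-in line and a difference between the 2 cell populations cannot be told apart for this excess, because the 2 fits with the covariate disagree.

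Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 335 called probes. The highest of the others gave 1 probe. This does not exclude a chance arrangement of the arrays, as 35 splits are few and the test was chosen after the results were seen. Every other split also mixes the groups, which adds any steady difference between them to its spread. For the number of probes at an unadjusted p under 0.05, a chance arrangement cannot be excluded either. There, 3 of the 35 splits gave as many as the real split's 20169. The highest other, 59072, came from the split of parental A and resistant B, C and D against the rest, which are the 4 arrays with the highest spike-in signals, and points to a structure of the samples other than the groups. Over all arrays with the spike-in signal as covariate, 6680 probes were called between the groups.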

How the results depend on the processing

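The fits without resistant A and B and those with the spike-in covariate were chosen after the data were seen. Counts are given as all called probes, those higher in resistant cells, and those with a fold of 2 or more; the group-only fit gave 335, 184 and 213. Renewed quantile normalization, the 75th percentile shift and both filters on dim probes stayed within 1.5 times of these. The trended robust prior gave 580 and 289, with the fold-2 count within 1.5 times. Array weights, which put resistant B at 0.057 and resistant C at 9.76, gave 97045, 52837 and 4388. The Student t-test gave 1010 and 476, with the fold-2 count within 1.5 times, and treat against a fold of 1.5 gave 13, 13 and 13. An unadjusted p with a fold of 2 gave 2442 probes, 501 higher, by limma and 1647, 438 higher, by the Student t-test. Leaving out resistant A and B gave 34293, 14849 and 2805, the spike-in covariate 6680, 3620 and 1234, and both together 3632, 1439 and 1369. Leaving out 1 array at a time gave 11 to 3483 called probes, 11 to 1607 higher ones and 11 to 1531 with a fold of 2; the highest came without resistant B or resistant A, and the fits without resistant C, resistant D or a parental array gave 15 or fewer. The replicate block (letters A to D) gave 0, 0 and 0 calls by limma, with 11774 probes at an unadjusted p under 0.05; the letters share only a name, and no parental array (0 of 4) matched the resistant array of its own letter best. The 4 named probes kept their direction in all 20 alternatives, with log2 changes of 3.08 to 3.25 and 2.73 to 3.21 for the 2 that rose, and -4.34 to -3.19 and -2.74 to -2.27 for the 2 that fell; their calls were lost in 1, 6, 9 and 8 of the 20, with adjusted p up to 0.32, 0.37, 0.64 and 0.58. The cause of these changes was not tested beyond the spike-in covariate. Alternatives for genes, HDAC9 and gene lists were not run, as probes carry no gene name, and signal over background could not be judged without detection calls.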

Other observations

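Changed probes of the custom sets tended to carry adjacent numbers. This was noticed in the data; the pairs were counted to check it, and the test of the spike-in line below was chosen after other results on it were seen. In the larger custom set, 62 pairs of adjacent numbers were both called in the same direction, and the highest of 10000 shuffles of the calls over the set gave 3 (permutation p = 1e-04, one-sided, the smallest that these shuffles can give). The smaller custom set had 12 such pairs against at most 2 in the shuffles. The longest stretch in the larger set held 11 probes in a row that were higher in resistant cells, by 0.88 to 1.19 on the log2 scale. Group differences of adjacent probes correlated across the larger set at r = 0.32, computed from resistant C and D and parental B, C and D, and probes 100 places apart at r = 0.03 (across probes, which are not independent replicates).

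Whether adjacent numbers in the custom sets target related transcripts, such as several products of one locus, was not tested: the 62 pairs only restate what had been noticed, and any cause of adjacency would give them. The alternative that neighbours merely share the spike-in line was first tested by correlation. Adjacent group differences (r = 0.32) exceeded adjacent deviations of parental A (r = 0.16), which by the bound first set argued against it. The difference of resistant B from resistant C and D, compared next, correlated at r = 0.28 between adjacent probes and left the alternative undecided. Another test was then chosen. The alternative predicts that the pairs fall to the shuffled level once the spike-in signal is in the fit. With that covariate 1111 same-direction pairs were called against at most 107 in the shuffles. This does not decide it, as the covariate raised the calls in the larger set from 194 to 3751. The shuffles also remove any likeness between neighbours, whatever its cause. Signal levels of adjacent probes correlated too (r = 0.42). Neighbours were alike in the difference of resistant B from resistant C and D (r = 0.28), but whether that reflects the line was not tested. Whether neighbours detect separate transcripts or share sequence stays open without probe sequences, and the called probes may not all be independent changes.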
